A study of Homo sapiens with 6 samples.

How the data were processed

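Polyadenylated RNA of human regulatory T cells was sequenced in 6 libraries, 3 from cells given a pool of guide RNAs (gRNAs) against ARG2 and 3 from cells given a scrambled gRNA. Per the labels' protocols, RNA was extracted on spin columns and libraries were made with a stranded TruSeq mRNA kit for 50 bp paired-end reads. The submitters' processing notes name TopHat2 2.0.12 for spliced alignment, SAMtools, HTSeq 0.6.1p1 for counting and the human builds hg19 and GRCh37. The annotation release, filters and the strand setting used in counting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart with certainty.

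The authors deposited 1 table of raw counts per Ensembl gene ID, with 1 column per library and no normalization. The table also holds 5 HTSeq summary rows that name no gene, and these were kept out of library sizes and tests. Reads in no annotated feature made up 6.85% to 9.76% of the column totals, ambiguous reads 2.61% to 2.80% and reads without a unique alignment 18.2% to 23.0%, while the other summary rows were 0. Reads without a unique alignment were not assigned to genes, so the levels of genes with near-identical copies, such as ribosomal protein genes and their pseudogenes, are uncertain.

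Of 63677 gene IDs, 39699 were matched to a gene name through a table of IDs and symbols, and older symbols in the gene lists were matched through the synonyms of the GRCh38.p14 assembly's gene table. Since that assembly differs from the build of the counts, it was used only for names, chromosomes, GC content and transcript length, and no coordinates are given. Y-linked genes and XIST were left out (474 IDs, with pseudoautosomal copies). A count above 0 in some library was found for 33659 IDs, and 15283 of them, 13952 with a name, passed edgeR's filterByExpr for the 2 groups.

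The main test was edgeR's quasi-likelihood test with robust dispersion estimates and TMM library sizes, on group alone, with Benjamini-Hochberg adjustment and a threshold of 0.05 (edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, mgcv 1.9.3, R 4.3.3). Log2 fold changes are ARG2 gRNA minus scrambled gRNA. Levels are CPM, counts scaled to a fixed library size after TMM scaling, and per-library log2 values carry a prior count of 2. The ARG2 transcript was tested by its own coefficient and by a two-sided exact permutation test.

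Before the data were examined, 25 gene lists were written down, covering Treg identity, effector T cell genes, arginine and polyamine metabolism, amino acid sensing, energy metabolism, proliferation, stress responses, the chromosomal neighbours of ARG2 and markers of other cell types. The 22 lists with at least 5 tested members went into limma's camera with a preset correlation of 0.01, camera with an estimated correlation, and fry. Within a list, genes were also adjusted over the list alone.

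The genes named in the text follow a rule made at the same time. It took ARG2, then up to 12 genes per direction past the threshold with a mean of at least 2 CPM and no overlap between groups. Where fewer than 5 passed in a direction, the 8 with the smallest unadjusted p under the same conditions were named as not passing. Immunoglobulin, T cell receptor and HLA genes, Y-linked genes, XIST and IDs without a name were excluded from this part. The rule further took from each list the 2 members with the smallest p in each direction, and from lists of other cells the 2 members with the highest CPM. Genes outside it are said to have been chosen after their values were seen. A member of the gene lists that the rule selects is not reported here.

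The groups share the replicate numbers 1 to 3 in the sample titles, so it was checked whether equal numbers deviate together from their group means. The correlations of deviations across genes were 0.66 for number 1, 0.48 for number 2 and 0.46 for number 3. Deviations cancel out within a group, so the outlying libraries numbered 1 alone push those numbered 2 and 3 towards positive correlations. ARG2 gRNA library 3 correlated at 0.49 with scrambled library 2, and ARG2 gRNA library 2 at 0.43 with scrambled library 3. The data therefore do not separate numbers 2 and 3, and their pairing rests on the titles alone. The numbers were treated as pairing the samples in a fit with the number as a block. No label says that a number marks a donor or a culture. The closest pair of libraries had a chi-square of 3.97 per gene over genes with at least 20 counts, so no library was a repeat of another within sampling noise.

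Alternatives to the main test were the replicate block, other library scalings, no filter or a stricter one on low counts, DESeq2, limma-voom, non-robust dispersion, omission of immune receptor and HLA genes, and omission of each library in turn. Offsets for GC content and transcript length, and a fit on the libraries numbered 2 and 3 alone, were added after seeing the data. GC content and length were known for 97.2% of the tested genes.

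Tests were run first on simulated counts drawn from the means and library sizes of these libraries. Noise was drawn independently for each library, and changed genes were taken from those with an average log2 CPM above 1. In the 3 against 3 design on group alone, 0 of 67 genes changed 1.5-fold, 6 of 67 changed 2-fold and 57 of 66 changed 4-fold were recovered, with 2 unchanged genes called. With the replicate block, 11 of 67, 53 of 67 and 66 of 66 were recovered, with 6 unchanged genes called. With 2 libraries per group and the spread of the libraries numbered 2 and 3, 50 of 67, 65 of 67 and 66 of 66 were recovered, with 19 unchanged genes called. For the lists, glycolysis genes were doubled in the ARG2 gRNA group of simulated independent genes. Camera called that list with either correlation, and 1 other list with the preset correlation but 0 with the estimated one. The hypoxia and p53 lists share members with glycolysis, so the other call need not be false.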

Results

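The series compared the transcriptomes of human regulatory T cells (Tregs), the FOXP3-expressing T cells that restrain immune responses, after CRISPR targeting of ARG2 or delivery of a scrambled gRNA. ARG2 encodes arginase 2, a mitochondrial enzyme that converts arginine to ornithine and urea, and the comparison asks what changes in the Treg transcriptome when this gene is targeted. The labels describe the cells both as expanded Tregs and as sorted from digested melanoma tumours, without the steps between. Each group held 3 libraries, with 21563052 to 26492734 counts assigned to genes per library. No label says whether the replicates came from separate donors or cultures, so p-values measure only the spread between these samples, which may be technical.

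ARG2 (ENSG00000081181, chromosome 14) was lower in the ARG2 gRNA libraries, at 53.3 ± 10.3 CPM (SD, n = 3) against 91.6 ± 12.5 CPM (SD, n = 3) with the scrambled gRNA. The transcript was thus still present, at 58.2% of the scrambled level (95% interval 42.4% to 80.0%). The ARG2 gRNA libraries 1, 2 and 3 held 1573, 1147 and 1001 ARG2 counts, or 64.8, 50.2 and 45.0 CPM. The scrambled gRNA libraries 1, 2 and 3 held 2165, 2639 and 1732 counts, or 96.5, 101 and 77.3 CPM. Each ARG2 gRNA library lay below each scrambled library, and within equal replicate numbers ARG2 stood at 67.2%, 49.7% and 58.2% of the scrambled value. The log2 fold change of ARG2 was -0.78 (SE 0.195), with an adjusted p of 1.00 over all 15283 genes by edgeR. For ARG2 alone, edgeR's quasi-likelihood test gave p = 0.00491 and the two-sided exact permutation test p = 0.1, the smallest that 3 against 3 libraries allow. A gRNA directs DNA cleavage, and the mRNA level does not measure the share of edited alleles or the arginase 2 protein.

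**Figure D1:**
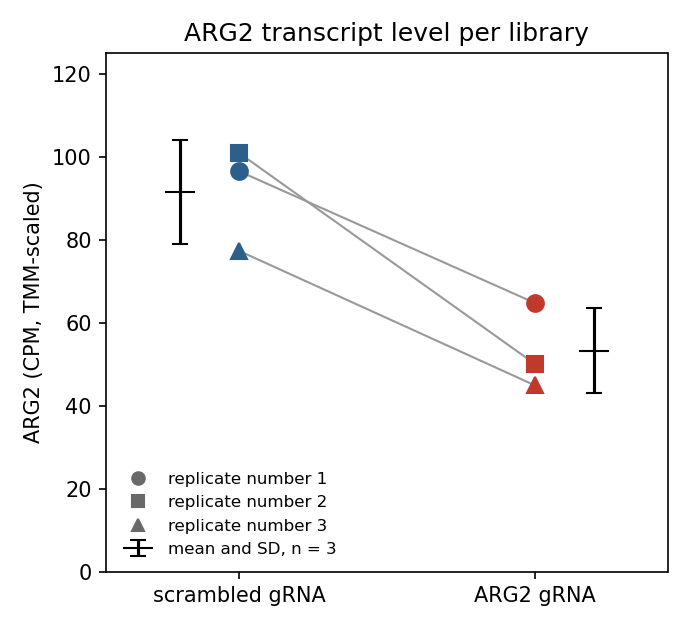
ARG2 transcript level (y axis, CPM on TMM-scaled library sizes) in each library of the scrambled gRNA and ARG2 gRNA groups (x axis). Marker shapes give the replicate number, grey lines join equal numbers, and black bars are the mean and SD of 3 libraries; the ARG2 gRNA libraries lie between 45.0 and 64.8 CPM, below the scrambled libraries at 77.3 to 101 CPM.

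ARG2 had the smallest p of all genes when the libraries numbered 1 were left out, an alternative chosen after seeing the data because these libraries stood apart (described next). The top rank was not limited to that fit. ARG2 also ranked first in the planned fits with the replicate block, DESeq2, the stricter filter on low counts and without ARG2 gRNA library 1. Its rank was 3 in the main test and 2 to 9 in the other planned fits. In the libraries numbered 2 and 3, ARG2 had a log2 fold change of -0.90 (SE 0.120) and was the 1 gene of 15189 past the threshold, with an adjusted p of 0.00328 by edgeR. In simulated libraries of this 2 against 2 design, edgeR called 19 unchanged genes beside the changed ones, so this adjusted p may be too small. The genes flanking ARG2 on chromosome 14 did not share its shift. Of 12 tested neighbours, 4 were higher and 8 lower, with a median log2 fold change of -0.07 and none past the threshold. Among them RDH11, a retinol dehydrogenase, had a log2 fold change of 0.09 (SE 0.169), ZFYVE26 -0.15 (SE 0.162), PALS1 -0.31 (SE 0.333) and TMEM229B 0.44 (SE 0.681).

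Most of the variation between libraries set the libraries numbered 1 apart from the other 4 and did not follow the gRNA. Both libraries numbered 1 lay apart from the other 4 on the first principal component of log2 CPM, which held 67.1% of the variance, and from each other on the second, which held 17.3%. Across genes, Pearson's r of log2 CPM was 0.991 to 0.992 among the 4 libraries numbered 2 and 3, 0.941 to 0.959 between these and the libraries numbered 1, and 0.969 between the libraries numbered 1. Mitochondrially encoded transcripts made up 8.57% of counts in ARG2 gRNA library 1 and 6.05% in scrambled library 1, against 4.59% to 4.76% in the other 4 libraries. The biological coefficient of variation was 32.6% on group alone, 17.3% with the replicate block and 8.67% in the libraries numbered 2 and 3.

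**Figure D2:**
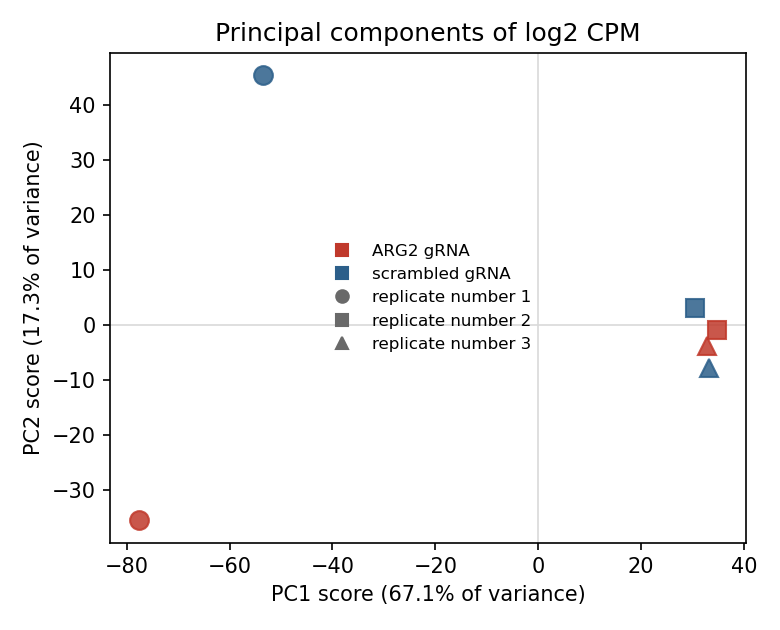
First and second principal component scores (x and y axes, no unit) of log2 CPM for the 6 libraries, with colour for the gRNA and shape for the replicate number. The components hold 67.1% and 17.3% of the variance; the 4 libraries numbered 2 and 3 lie close together at the right, and both libraries numbered 1 lie apart at the left.

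No gene passed the threshold over all genes between the ARG2 gRNA and scrambled gRNA groups. Among the genes named for their small unadjusted p, RPLP0P9, a ribosomal protein pseudogene, lay furthest above its scrambled level, and ADAM32, a member of the ADAM metalloprotease family, furthest below. Among 15283 genes, edgeR called 0, with 48 at an unadjusted p under 0.05, and limma-voom called 0 with 50. DESeq2 was run without that filter on 33552 genes and called 0, with 108 such genes. The 3 libraries of each group did not overlap for 523 genes, 3.42% of those tested, where chance gives 10% if libraries are interchangeable. They were not, since shared deviations of the libraries numbered 1 make overlap between the groups more likely, whatever the gRNA does. The 10% is thus no benchmark here. For the same reason the 48 genes lie far below the share of 0.05 that interchangeable libraries would give. In simulated libraries with the same spread per gene, 8.96% of genes changed 2-fold and 86.4% of those changed 4-fold were recovered on group alone. With the replicate block 79.1% and 100% were recovered, and 16.4% of those changed 1.5-fold. The simulated noise was independent between libraries, while real deviations were shared by the libraries numbered 1. The shares on group alone therefore need not hold for these data. Changed genes were drawn only from those with an average log2 CPM above 1.

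The 8 named genes with higher values in the ARG2 gRNA libraries did not pass. RPLP0P9 averaged 8.05 ± 1.81 CPM (SD, n = 3) against 4.94 ± 0.927 CPM, a log2 fold change of 0.70 (SE 0.281), and its reads can be confused with those of RPLP0. FTH1P2, a ferritin heavy chain pseudogene with the same limit, stood at 0.50 (SE 0.235). The zinc finger genes ZNF57 and ZNF511 had log2 fold changes of 0.62 (SE 0.291) and 0.38 (SE 0.175). The transmembrane protein genes TMEM187 and TMEM186 stood at 0.64 (SE 0.282) and 0.47 (SE 0.224). ANKRD54, an ankyrin repeat protein gene, was at 32.8 ± 8.97 CPM against 23.4 ± 1.32 CPM, a log2 fold change of 0.48 (SE 0.218). PFDN2, a subunit of the prefoldin chaperone that assists actin and tubulin folding, stood at 0.39 (SE 0.182). In all 8 the difference within replicate number 1 was larger than within numbers 2 and 3.

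The 7 named genes other than ARG2 with lower values did not pass either, and most were near 2 CPM. USP6, a ubiquitin-specific protease gene, averaged 1.83 ± 0.466 CPM (SD, n = 3) against 3.63 ± 0.515 CPM, a log2 fold change of -0.98 (SE 0.321). ADAM32 stood at -1.05 (SE 0.427) and NAP1L3, a nucleosome assembly protein family gene, at -0.86 (SE 0.302). CDON, a cell surface receptor of the hedgehog pathway, stood at -0.80 (SE 0.316) and CA13, a carbonic anhydrase, at -0.78 (SE 0.313). TMEM45A was at 5.56 ± 0.676 CPM against 8.73 ± 2.29 CPM. ANKRD10-IT1, an RNA transcribed within ANKRD10, was at 5.53 ± 0.722 CPM against 8.76 ± 2.04 CPM, and its reads cannot be fully separated from those of its host gene. The unadjusted p of these 7 genes ranged from 0.0174 for USP6 to 0.0445 for TMEM45A by edgeR.

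**Figure D3:**
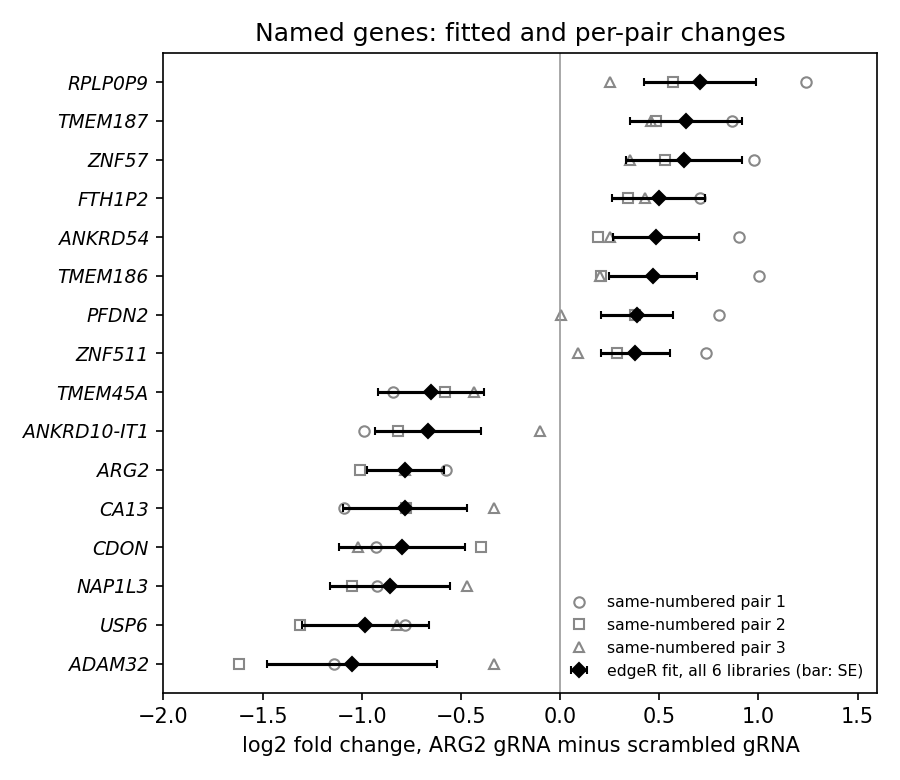
Log2 fold changes (x axis, ARG2 gRNA minus scrambled gRNA) of the 16 named genes (y axis). Black diamonds with SE bars are the edgeR fit over 6 libraries and open markers the differences within equal replicate numbers; ARG2 lies at -0.78, and the higher genes show their largest difference in pair 1.

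Transcripts of the translation and respiration machinery were slightly higher in the ARG2 gRNA group. Of 52 ribosomal protein genes 51 were higher, with a median log2 fold change of 0.15, as were 39 of 54 nuclear-encoded subunits of oxidative phosphorylation (median 0.11), 14 of 15 mitochondrially encoded genes (median 0.20) and 21 of 29 ribosome biogenesis genes (median 0.05). Their adjusted p by limma's camera with a preset correlation was 2.04e-07, 0.00144, 0.00415 and 0.0121, and with the replicate block 8.2e-10, 0.00257, 1.1e-05 and 0.0695, so that ribosome biogenesis no longer passed. With an estimated correlation no list passed: the adjusted p was 0.797 for oxidative phosphorylation and 0.857 for the other 3 lists, and fry gave an adjusted p of 0.973 for each list. No single member of these lists passed, over all genes or adjusted over the list alone.

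The direction of these lists was not shared by the 3 same-numbered pairs. The median log2 difference of ribosomal protein genes was 0.35 in pair 1, 0.14 in pair 2 and -0.10 in pair 3, and that of oxidative phosphorylation genes was 0.26, 0.11 and -0.06. Mitochondrially encoded genes were at 0.53 in pair 1, where the mitochondrial share of counts was also highest, and at -0.02 and -0.03 in pairs 2 and 3. Ribosome biogenesis genes were at 0.18, 0.10 and -0.09. Ribosomal protein and mitochondrially encoded genes did not pass without ARG2 gRNA library 1, where their medians were -0.02 and -0.06. That fit leaves scrambled library 1 without a partner, so gRNA and replicate number cannot be told apart in it. Oxidative phosphorylation genes did not pass without ARG2 gRNA library 1 or 2, and ribosome biogenesis genes not without ARG2 gRNA library 2 or 3 or scrambled library 1. In the libraries numbered 2 and 3 alone only the ribosomal proteins of these 4 lists passed (adjusted p = 0.0404 by camera with a preset correlation, 0.836 with an estimated one). Leading members with their fitted log2 fold changes were RPS19 (0.23, SE 0.160), RPL8 (0.28, SE 0.217), the complex I subunits NDUFB9 (0.28, SE 0.176) and NDUFA9 (0.38, SE 0.269), the mitochondrial ribosomal RNAs MT-RNR2 (0.22, SE 0.163) and MT-RNR1 (0.29, SE 0.232), and the ribosomal RNA processing factors RRP12 (0.28, SE 0.183) and NOP16 (0.28, SE 0.185). Members on the other side were RPL15 (-0.03, SE 0.151), the succinate dehydrogenase subunit SDHD (-0.18, SE 0.192), cytochrome c (CYCS, -0.28, SE 0.300), MT-ND4L (-0.04, SE 0.192), and the RNA polymerase I genes POLR1B (-0.18, SE 0.266) and RRN3 (-0.11, SE 0.180).

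**Figure D4:**
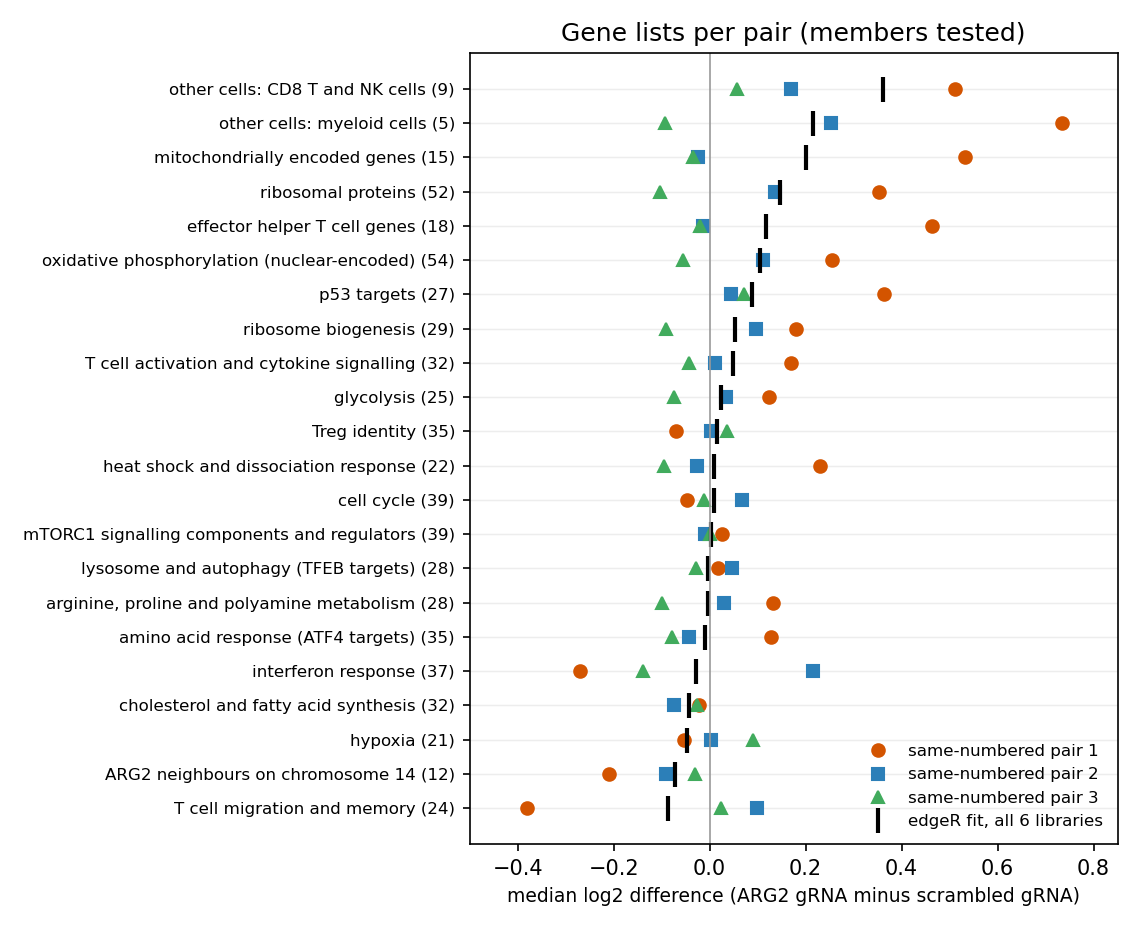
Median over tested members of the log2 difference (x axis, ARG2 gRNA minus scrambled gRNA) for the 22 gene lists tested (y axis, members in parentheses). Coloured markers are the 3 same-numbered pairs and black ticks the edgeR fit over 6 libraries; pair 1 lies furthest from 0 for most lists, and for ribosomal proteins the pairs lie at 0.35, 0.14 and -0.10.

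Treg identity genes were balanced between the groups. Of 35 tested members 19 were higher and 16 lower, with a median log2 fold change of 0.02 and an adjusted p of 0.764 by camera with a preset correlation. FOXP3, the lineage-defining transcription factor, had a log2 fold change of 0.11 (SE 0.21), and IL2RA, the high-affinity interleukin-2 receptor chain, 0.21 (SE 0.24), both named after their values were seen. TNFRSF18, which encodes the costimulatory receptor GITR, stood at 0.50 (SE 0.313) and the transcription factor BATF at 0.48 (SE 0.331), with pair differences of 1.38 and 1.02 in number 1 against -0.24 to 0.17 in numbers 2 and 3. METTL7A (-0.41, SE 0.265) and STAM (-0.30, SE 0.205) led on the lower side.

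Other T cell programmes did not pass. Of 18 effector helper T cell genes 12 were higher (median 0.12, adjusted p = 0.134 by camera), with CXCR3 at 0.25 (SE 0.205), IL18RAP at 0.40 (SE 0.344), RORA at -0.36 (SE 0.328) and IL23R at -0.49 (SE 0.443). The median of this list was 0.46 in pair 1 and -0.01 and -0.02 in pairs 2 and 3. Of 32 genes of activation and cytokine signalling 19 were higher (adjusted p = 0.482), among them the inhibitory receptor gene LAG3 at 0.30 (SE 0.256) and IL2RG at 0.15 (SE 0.146), with EGR1 at -0.39 (SE 0.537) and HLA-DRA at -0.11 (SE 0.176). Of 24 migration and memory genes 16 were lower (median -0.09, adjusted p = 0.271), with the integrin genes ITGB1 at -0.30 (SE 0.214) and ITGA1 at -0.89 (SE 0.594, mean level only 0.68 CPM) and, on the higher side, SELPLG at 0.10 (SE 0.353). Their median was -0.38 in pair 1 and 0.10 and 0.02 in pairs 2 and 3, and in the libraries numbered 2 and 3 alone the list passed towards higher values (adjusted p = 0.0306 by camera with a preset correlation, 0.803 with an estimated one).

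Arginine, proline and polyamine metabolism, the pathway in which ARG2 acts, showed 14 members higher and 14 lower (median -0.00, adjusted p = 0.764 by camera). The hypusine enzyme DOHH stood at 0.32 (SE 0.270) and spermidine synthase (SRM) at 0.25 (SE 0.232), while CPS1, which makes carbamoyl phosphate, stood at -0.67 (SE 0.400) and the mitochondrial ornithine carrier SLC25A15 at -0.21 (SE 0.224). ARG1, the cytosolic arginase, was at 0 to 0.16 CPM in the 6 libraries and was not tested. ODC1, which turns ornithine into putrescine, was at 0.01 (SE 0.143); both were named after their values were seen. Amino acid response genes controlled by ATF4 had 15 members higher and 20 lower (median -0.01, adjusted p = 0.350), including ATF3 (0.39, SE 0.293), DDIT3 (0.26, SE 0.203), SLC38A2 (-0.25, SE 0.196) and PSPH (-0.28, SE 0.256). The list of components and regulators of mTORC1, which responds to arginine and other amino acids, had 20 members higher and 19 lower (median 0.00, adjusted p = 0.785). They included WDR24 (0.28, SE 0.209), EIF4EBP1 (0.25, SE 0.208), SESN3 (-0.88, SE 0.541) and RICTOR (-0.36, SE 0.309), a subunit of the related complex mTORC2. In the libraries numbered 2 and 3 alone, the ATF4 list passed towards lower values (median -0.04, adjusted p = 0.00436 by camera), and no longer with an estimated correlation (adjusted p = 0.803).

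Glycolysis genes had 16 members higher and 9 lower (adjusted p = 0.350 by camera), with ENO2 at 0.21 (SE 0.246), GAPDH at 0.11 (SE 0.160), PFKFB3 at -0.18 (SE 0.389) and LDHB at -0.07 (SE 0.178). Cholesterol and fatty acid synthesis had 12 higher and 20 lower (adjusted p = 0.959), with EBP at 0.32 (SE 0.268), NSDHL at 0.17 (SE 0.150), SC5D at -0.23 (SE 0.194) and FADS1 at -0.20 (SE 0.182). This list passed downward without scrambled library 1 (median -0.10, adjusted p = 0.0329 by camera with a preset correlation, 0.705 with an estimated one). Lysosome and autophagy genes had 13 higher and 15 lower (adjusted p = 0.764), with NEU1 at 0.27 (SE 0.214), CTSL at 0.18 (SE 0.143), ATP6V1A at -0.41 (SE 0.266) and RRAGD at -0.26 (SE 0.226). Cell cycle genes had 22 higher and 17 lower (adjusted p = 0.440), with GINS2 at 0.25 (SE 0.177), CDC25A at 0.21 (SE 0.178), CCNA2 at -0.15 (SE 0.347) and CENPE at -0.10 (SE 0.250). The direction of the glycolysis, cell cycle, ATF4, interferon and hypoxia lists depended on which library numbered 1 was left out. All 5 passed upward by camera with a preset correlation without ARG2 gRNA library 1 (adjusted p from 1.09e-09 to 0.0191) and downward without scrambled library 1 (0.00444 to 0.0172), but not with an estimated correlation (adjusted p = 0.711 and 0.705). The glycolysis, cell cycle and ATF4 lists also passed upward without scrambled library 2 or 3. The interferon list did so without scrambled library 3, and all of these again only with a preset correlation. Fits with 1 library left out were on group alone. They give the libraries numbered 1, where most members of the 5 lists were lowest, unequal weight in the groups. The directions are those that this imbalance gives, so they say little about the gRNA.

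Stress programmes did not pass over the 6 libraries. Of 27 p53 targets 18 were higher (median 0.09, adjusted p = 0.271 by camera), with TNFRSF10C at 1.16 (SE 0.910, mean level only 0.35 CPM), TRIAP1 at 0.24 (SE 0.219), TP53INP1 at -0.55 (SE 0.365) and RRM2B at -0.31 (SE 0.300). Their median was positive in each same-numbered pair, at 0.36, 0.04 and 0.07, and in the libraries numbered 2 and 3 alone the list passed (adjusted p = 0.000951 by camera with a preset correlation, 0.803 with an estimated one). With 1 library left out the p53 list also went both ways. It passed upward without ARG2 gRNA library 1 (median 0.33) and without scrambled library 2 or 3. In each case this held only with a preset correlation (adjusted p = 0.711, 0.866 and 0.616 by camera with an estimated one). Its median was -0.18 without scrambled library 1, -0.01 without ARG2 gRNA library 3 and 0.06 without ARG2 gRNA library 2, and it did not pass there. These fits, on group alone, give the libraries numbered 1 unequal weight in the groups, and 18 of 27 p53 targets were lowest in both. Except for the median without ARG2 gRNA library 2, the signs are those that this imbalance gives. These fits therefore say little about the pair medians. Interferon response genes went both ways, with medians of -0.27, 0.21 and -0.14 in pairs 1, 2 and 3 and an adjusted p of 0.998, and IFI6 (0.28, SE 0.253), BST2 (0.38, SE 0.351), STAT2 (-0.11, SE 0.179) and ISG20 (-0.10, SE 0.188) as leading members. Hypoxia genes had 7 higher and 14 lower (adjusted p = 0.943), with P4HA2 at 0.48 (SE 0.369), ZNF395 at 0.12 (SE 0.147), MXI1 at -0.35 (SE 0.283) and BNIP3L at -0.34 (SE 0.324). Heat shock and dissociation genes had 14 higher and 8 lower (adjusted p = 0.440), with IER3 at 0.75 (SE 0.461), DUSP1 at -0.80 (SE 0.366) and HSPA1B at -0.25 (SE 0.275). Their list passed upward without scrambled library 3 (adjusted p = 0.0396 by camera with a preset correlation, 0.616 with an estimated one). Its median was -0.13 without scrambled library 1, where it did not pass. For arginine metabolism, the ATF4 list, mTORC1, the cell cycle, lysosome and hypoxia lists, the sign of the median or mean differed from the direction of the camera test, which was upward in each.

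Most markers of other cell types were low, with exceptions such as CST7, PRF1, ITGAM and IGHM. CCL5, IGKC and PECAM1 were at 0 in every library under their listed IDs; a mismatch of IDs between annotation releases was not excluded, so they were not counted as low. All 9 tested CD8 T and NK cell markers were higher in the ARG2 gRNA group (median log2 fold change 0.36, adjusted p = 0.0347 by camera, 0.797 with an estimated correlation), with their largest pair median, 0.51, in pair 1. This list did not pass when any 1 of the 6 libraries was left out, and the myeloid list passed only without ARG2 gRNA library 1 or scrambled library 3, and there not with an estimated correlation (0.711 and 0.604). Their most abundant members, CST7 and PRF1, stood at 0.39 (SE 0.950) and 0.10 (SE 0.176). All 5 tested myeloid markers were higher as well (median 0.22, adjusted p = 0.0185 by camera, 0.797 with an estimated correlation), at 0.74 in pair 1 and -0.09 in pair 3. The most abundant, the integrin gene ITGAM, was at 0.06 (SE 0.935) and FCER1G at 0.24 (SE 0.315), and the remaining 3, AIF1, LYZ and CST3, stayed at or below 6.43 CPM in every library. B cell markers had 4 tested members, too few for a list test over the 6 libraries. Without ARG2 gRNA library 1 more were tested and the list passed downward (median -0.31, adjusted p = 0.0191 by camera, 0.711 with an estimated correlation). Scrambled library 1, where IGHM was high, then had no same-numbered partner, so this call cannot be told apart from the replicate number. IGHM was at 1168 and 1053 CPM in the libraries numbered 1 and at 76.2 to 104 CPM in the other 4, with a log2 fold change of 0.08 (SE 1.32), and CD79B stood at 0.24 (SE 0.270). Melanoma and stroma markers also had 4, with PDGFRB at 0.41 (SE 0.787) and COL1A2 at -0.86 (SE 0.484), and no marker of red cells or platelets was high enough to be tested, ITGA2B and HBB leading at means of 0.485 and 0.113 CPM.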

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

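The fit on the libraries numbered 2 and 3 alone and the offsets for GC content and transcript length were chosen only after the results were seen, and the other alternatives were planned. ARG2 stayed lower under all 18 alternatives, with log2 fold changes from -0.94 to -0.68, unadjusted p from 2.16e-07 to 0.0220 and adjusted p from 0.00328 to 1.00. The count of genes changed was 0 in each fit except that on the libraries numbered 2 and 3 alone, where 1 gene, ARG2, passed as lower and the common spread was smaller. With the replicate block ARG2 was at -0.79 (SE 0.152, adjusted p 0.973 by edgeR), and 0 genes passed, with 202 at an unadjusted p under 0.05; the block ended the call of the ribosome biogenesis list (5 lists passing in place of 6) and changed no other call, and GC and length offsets with the block brought that call back (adjusted p 0.00467 by camera, 6 lists). The offsets without the block ended the call of the CD8 T and NK cell list (5 lists), and the filter at 2 CPM left 4 lists, without the CD8 T and NK cell and myeloid lists. GC and length offsets with the block left 0 genes, the smallest adjusted p being 0.643. The 15 other named genes kept their sign in all 270 refits. They were chosen for groups that do not overlap, so their sign could hardly turn, and this adds no support. Of the gene lists, 6 passed in the main test with a preset correlation, 2 without a filter on low counts, 0 with an estimated correlation and 0 by fry. Leaving out 1 library gave 2 to 11 lists: 9 without ARG2 gRNA library 1, 2 without ARG2 gRNA library 2, 3 without ARG2 gRNA library 3, 9, 8 and 11 without scrambled libraries 1, 2 and 3. These counts hold for a preset correlation; with an estimated one 0 lists passed in each (smallest adjusted p 0.604 by camera). Each of these fits, on group alone, gives the libraries numbered 1 unequal weight in the 2 groups. The ATF4, glycolysis, cell cycle, interferon and hypoxia lists passed upward without ARG2 gRNA library 1 and downward without scrambled library 1. Most of their members that passed the test of the replicate number (below) were lowest in both libraries numbered 1. In list order these were 12 of 13, 11 of 12, 21 of 21, 23 of 24 and 7 of 8. Both directions are therefore those that the imbalance gives, and they say little about the gRNA. The other changes were not tested for a cause. DESeq2, limma-voom in place of edgeR and non-robust dispersion were not run for the lists, because camera takes voom values already. Depth was alike across libraries, at 21563052 to 26492734 counts, where 3 counts equal 0.113 to 0.139 CPM.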

Other observations

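The test of the replicate number, the marker tests for other cells, the neighbour test, the GC and length test of ARG2 and the count of splits were chosen only after the results were seen; the GC and length tests on the libraries numbered 1 were set out beforehand, and the other scalings and the replicate block were set out beforehand as other ways of fitting and weighed as explanations afterwards. The replicate number, mainly number 1 against the others, carried more of the transcriptome than the gRNA did. In the fit with number and gRNA as terms, 2339 of 15283 genes (15.3%) passed edgeR's test for the number at an adjusted p under 0.05. Of 35 Treg identity genes 17 passed, 10 with both libraries numbered 1 highest and 7 with both lowest; the genes named here were chosen after their values were seen. CTLA4, an inhibitory receptor central to Treg function, was at 1165 and 828 CPM in the ARG2 gRNA and scrambled libraries numbered 1 and at 274 to 301 CPM in the other 4 (adjusted p = 0.000123 by edgeR). ENTPD1, which encodes the ectonucleotidase CD39, was at 199 and 230 CPM against 32.0 to 40.5 CPM, and TIGIT at 596 and 673 CPM against 174 to 216 CPM. PDCD1, the gene of PD-1, was at 79.0 and 46.1 CPM against 8.13 to 9.67 CPM, and CD27 at 705 and 512 CPM against 227 to 244 CPM. On the lower side, the interleukin-1 receptor genes IL1R2 and IL1R1 were at 24.9 and 12.8 CPM against 64.5 to 83.7 CPM and at 71.7 and 83.4 CPM against 161 to 190 CPM. FOXP3 did not pass this test, at 760 to 1220 CPM over the 6 libraries (adjusted p = 0.198).

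Interferon and cell cycle genes that passed were mostly lowest in both libraries numbered 1, while those of activation and cytokine signalling went both ways, with 11 of 23 lowest and 12 highest. CISH and SOCS2, feedback inhibitors induced by interleukin-2 through STAT5, were at 29.2 to 39.2 and 8.60 to 10.9 CPM there, against 269 to 380 and 94.2 to 119 CPM in the other 4 libraries. Of 37 interferon response genes 24 passed the test for number, 23 of them with both libraries numbered 1 lowest, such as MX1 at 31.1 and 31.9 CPM against 78.3 to 114 CPM. Of 39 cell cycle genes 21 passed, all with both libraries numbered 1 lowest, such as MCM6 at 231 and 296 CPM against 578 to 658 CPM. The same held for 11 of 12 glycolysis genes that passed, 12 of 13 p53 targets and 12 of 13 ATF4 targets, among them SLC7A11, a cystine transporter, at 12.1 and 14.9 CPM against 47.7 to 70.6 CPM. ASS1, which regenerates arginine from citrulline, was at 0.206 and 0.357 CPM against 2.83 to 4.87 CPM. The immunoglobulin heavy chain gene IGHM was at 1168 and 1053 CPM against 76.2 to 104 CPM.

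For the separation of both libraries numbered 1 from the other 4, B cells in these libraries were tested through MS4A1 and CD79A, which reached at most 5.88 CPM there while IGHM stood above 1000 CPM; this argues against B cells as the source of the whole separation. All 4 tested B and plasma cell markers were nevertheless highest in both libraries numbered 1, and 3 passed the test for number, with CD79A at 4.41 and 5.88 CPM against 1.03 to 1.84 CPM and MZB1 at 34.7 and 22.3 CPM against 12.9 to 14.9 CPM, so a small share of such cells stays open. The GC and length test argues against such trends as the whole cause. After their removal, the SD over 10300 genes of the difference between number 1 and the mean of numbers 2 and 3 was still 3.29 times that between numbers 2 and 3 in the scrambled group (95% interval over resampled genes 3.17 to 3.41) and 4.09 times in the ARG2 gRNA group (3.96 to 4.22). The intervals cover the resampling of genes, which are not independent replicates, and not the spread between libraries. A different donor, culture or time after stimulation may underlie the separation. None of these was tested, because the labels name none of them.

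The libraries numbered 1 also differed from each other more than the other same-numbered pairs, with an SD over genes of 0.524 against 0.196 and 0.149 on the log2 scale. Their difference followed GC content across genes, with Spearman's rho of 0.63 against 0.10 and -0.27 in pairs 2 and 3; genes are not independent replicates. Removing GC and length trends took away 40.7% of the variance in pair 1, and the SD stayed 2.10 times the larger of the other pairs' SDs (95% interval over resampled genes 2.05 to 2.15), so such trends may account for part of the difference but not for all of it. Cytotoxic or myeloid cells in ARG2 gRNA library 1 were tested through NKG7, GNLY, LYZ and S100A9, which reached at most 12.2 CPM there, and this argues against such cells as the source of the whole difference. NKG7 was nevertheless at 12.2 CPM there against 6.46 CPM in scrambled library 1, though at 12.4 to 16.8 CPM in the other 4, and the medians of the CD8 T and NK cell and myeloid lists in pair 1 were 0.51 and 0.74. Of other cytotoxic markers, CST7 and PRF1 were at 333 and 94.7 CPM there and at 235 and 84.4 CPM in scrambled library 1, and GZMB was at 17.3 CPM there, above its level in scrambled library 1 and below the 23.1 to 31.3 CPM of the other 4. A small share of such cells stays open. An effect of the gRNA in this pair alone, or a difference in RNA handling, stays open and untested.

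For the lower ARG2 level, library scaling was tested with the other scaling methods, under which the log2 fold change was -0.73 or lower, and a change of its whole neighbourhood with the 12 tested neighbours, whose median was -0.072 (SD 0.198). With GC and length offsets and the replicate block, ARG2 was at -0.72. These values argue against scaling, a change of the whole neighbourhood, and GC or length trends as the whole cause. The design names the ARG2 gRNA as a biological explanation, and lower transcript from edited alleles is a candidate explanation, as a hypothesis, since editing was not measured in the counts.

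The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. Each of the 10 splits gave 0 changed genes, the real one included (highest other 0), so this count says nothing about chance. For the gene lists, 6 of the 10 splits gave at least the 6 lists of the real split, with a highest other of 11. The splits with both libraries numbered 1 on the same side gave 9 to 11 lists. They gave 1404 to 1882 genes at an unadjusted p under 0.05 by edgeR, against 48 in the real split. This points to the separation of the libraries numbered 1 as a structure of the samples. Among the splits that part all 3 pairs, the others gave 2, 4 and 6 lists.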
